A study of Mus musculus with 6 samples.

How the data were processed

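PolyA RNA from flushed, pulverised tibia cortex was sequenced, per the labels' protocols. Libraries were grouped by the diet in their labels, 3 on the control diet and 3 on the adenine diet. The labels describe both a directional and a non-directional library preparation without saying which was used, and the genome build, annotation release and strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart with certainty. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 without a version and edgeR 3.22.5, with no role or order.

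The authors deposited a comparison table of 25721 genes and a table of FPKM for 56748 genes. The comparison table holds raw counts per gene and library, deposited by the authors without scaling. It also holds a normalized signal, which is the deposited counts divided by 1 size factor per library (0.825 to 1.20), as tested on the values. The deposited FPKM values use an effective library size, the count sum times a factor of 0.906 to 1.15 per library, and are equal in both tables within 4.97e-06. The authors' log2 fold changes, p-values and adjusted p-values are deposited in the same table. An own DESeq2 fit of the deposited counts gave log2 fold changes within 6.47e-05 of theirs and the same 361 calls, and the 7030 rows whose deposited adjusted p is 1 are as many as that fit leaves without an adjusted p. Every row of the comparison table has a count sum of at least 2; of the 31027 rows found only in the FPKM table, 969 hold a value above 0, and these rows entered no test. Gene coordinates are those of the files, with the last digit of the longest ones rounded. Of 52125 genes shared with a GRCm38 annotation, 2.92% had the same start and end, so the files use another build, which is not given in the sources used here, and no coordinates were mixed.

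The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; TMM scaling, glmQLFit with robust moderation, two-sided, group as the only term) on the deposited counts of the 15609 genes kept by filterByExpr with a minimum count of 10. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled. The median log2 fold change of all tested genes was near 0 (-3.85e-07). The biological coefficient of variation was 0.439. With 3 libraries against 3, a split-based test of a single value cannot give a share under 0.1.

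Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for 36 lists with at least 5 tested members, adjusted over the 36. Where 2 genes shared a symbol, the one with the higher mean was used, a rule set after seeing that glycolysis had such a pair. The lists cover citrate and energy metabolism, bone cells, mineral hormones, stress and signalling responses, and markers of other cell types that flushed bone can hold. Members were also counted adjusted over the list alone. The lists, the main test, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and falls past the threshold among protein-coding genes with non-overlapping groups and at least 1 FPKM, or, where none pass in a direction, the 4 with the smallest p. It also names a panel of 25 genes whatever their result, and up to 4 members of each called list by smallest p. Some genes that the rule would name are not used here, though they stay in the counts and list tests. The panel was fixed as names; adjusting over its 25 genes alone was not written down as a test beforehand and was computed when no gene had passed over all genes. A list of kidney tubule genes (20 genes, 18 tested) was added once the deposited comparison had been seen.

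The procedure was tested on simulated counts of 15609 genes drawn from these libraries' means. With the dispersions estimated from these libraries, edgeR recovered 0% of genes changed 2-fold and 48% of those changed 4-fold with 5 false calls, and DESeq2 9% and 82.8% with 53 false calls. With those dispersions divided by 4, edgeR recovered 60% and 98% with 11 false calls. Camera found the changed list and not the unchanged one. Each gene was drawn independently, so the simulation cannot tell how camera's preset correlation performs on the correlated genes of the real lists.

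Alternatives were DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), limma-trend on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, no filter on low counts, a filter with a minimum count of 50, prior counts of 0.1 and 10 in log2 CPM, haemoglobin, mitochondrial and muscle genes left out, the replicate number as a block, no robust moderation, each library left out, an estimated correlation, and fry. Chosen after seeing the data were the mean log2 CPM of the muscle list or of the kidney list as a covariate, leaving out control 3 and adenine 1 together, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 10), and limma voom.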

Results

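RNA was sequenced from the cortical bone of mouse tibiae whose ends had been removed and whose marrow had been flushed out. Wild-type mice received a control diet or a diet with 0.2% adenine by weight, which damages the kidney tubules and is used as a model of chronic kidney disease. The diet started at 8 weeks of age and lasted 4 weeks, and the bones were collected at 12 weeks. There were 3 libraries per diet, numbered control 1 to 3 and adenine 1 to 3. Total counts were 14598010, 10549071 and 13975659 in the control libraries and 9977694, 11238460 and 12044459 in the adenine libraries. The labels do not state that each library came from a separate mouse, so the p-values measure the spread between these samples. Spearman correlations of log2 CPM were 0.908 to 0.959 within the control group, 0.900 to 0.956 within the adenine group and 0.815 to 0.954 between the groups.

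The comparison asked how the adenine diet changed transcripts of cortical bone, and the series title points to citrate production by osteocytes, the cells embedded in bone matrix. Osteoclast genes were higher on the adenine diet: 12 of the 18 tested genes of this list, which covers the machinery of bone resorption, rose when adjusted over the list alone. Nerve and Schwann cell genes were lower, with 7 of 9 falling, and 11 of 20 genes of periosteal and tendon fibroblasts fell, again adjusted over the list alone. Among 25 genes of citrate and mineral metabolism and bone cells chosen before the data were examined, Slc13a5, Cyp24a1, Acp5 and Ctsk rose while Mepe and Tnfrsf11b fell, adjusted over these 25 alone. Only the gene names were fixed beforehand, and this adjustment was computed when no gene had passed over all genes. Genes of citrate synthesis and export as a group were not called in either direction. Over all 15609 genes tested, edgeR's quasi-likelihood test passed 0 genes in either direction (smallest adjusted p = 0.169), with 1671 genes at an unadjusted p under 0.05 against 780 expected by chance, while the DESeq2 Wald test passed 361. The panel count of 6 was 0 without control 1, control 2 or adenine 3, 1 without adenine 1, and 0 with the replicate number as a block or with the kidney tubule level as a covariate, the latter chosen after seeing the data. The 1671 was 1031, 2819 and 945 without control 1, 2 and 3 and 906, 3133 and 1098 without adenine 1, 2 and 3.

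Slc13a5 encodes the sodium-coupled citrate transporter of the plasma membrane. It (ENSMUSG00000020805, chromosome 11, 72132815 to 72158048 in the files' coordinates) was measured at 15.2 ± 6.93 CPM (SD, n = 3) on the control diet and 45.9 ± 21.4 CPM (SD, n = 3) on the adenine diet. The log2 fold change was 1.59 with a standard error of 0.46, and every adenine library lay above every control library (edgeR adjusted p = 0.0387 over the 25 genes alone and 0.324 over all genes). Cyp24a1, the vitamin D 24-hydroxylase (ENSMUSG00000038567, chromosome 2, 170324630 to 170339060), went from 0.278 ± 0.134 CPM to 4.37 ± 4.65 CPM (SD, n = 3 each), a log2 fold change of 3.91 with a standard error of 0.99. Its counts were 6, 2 and 3 in the control libraries and 105, 21 and 16 in the adenine libraries, so the fold rests on few control reads; with the kidney tubule level as a covariate, chosen after seeing the data, it was 1.88, and without adenine 1 it was 2.55. Mepe, which encodes a matrix phosphoglycoprotein of osteocytes (ENSMUSG00000053863, chromosome 5, 104473200 to 104486480), fell by 2.43 on the log2 scale with a standard error of 0.68. Its level in control 3, 19.8 CPM, lay within the adenine range of 14.3 to 22.8 CPM, whereas control 1 and control 2 had 109 and 154 CPM. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclast formation (ENSMUSG00000063727, chromosome 15, 54114015 to 54141880), fell from 19.2 ± 1.47 to 4.81 ± 2.57 CPM (SD, n = 3 each).

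**Figure D1:**
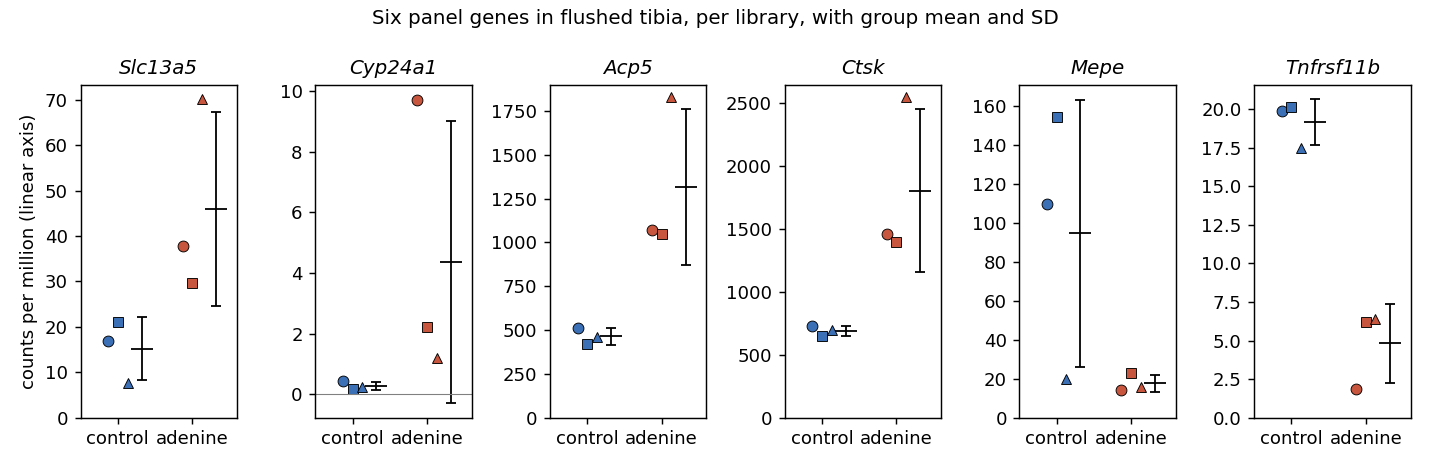
CPM, reads of a gene scaled to library size (linear vertical axes, one per gene) of the 6 panel genes that passed when adjusted over the 25 genes alone, in the 3 control (blue) and 3 adenine (red) libraries; circles, squares and triangles are libraries 1, 2 and 3, and black bars are group means ± SD. Slc13a5, Cyp24a1, Acp5 and Ctsk lie higher in all 3 adenine libraries than in any control library, Tnfrsf11b lies lower in all 3, and Mepe overlaps through control 3.

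The other 19 panel genes did not pass. Of the enzymes and carriers that make and move citrate, Cs (citrate synthase) had a log2 fold change of -0.50, Aco1 of 0.26, Acly of 0.05, Slc25a1 of 0.09 and Idh2 of -0.15, and Ank, a membrane protein that exports pyrophosphate and citrate, had -0.73. Standard errors of these values were 0.22 to 0.47. Of the osteocyte genes, Sost had -2.40, Dmp1 -0.998, Phex -0.75 and Fgf23 -0.49, the last at only 1.79 and 1.28 CPM in the control and adenine groups. The standard error of Sost was 0.91. Its level in control 3, 6.61 CPM, lay below the adenine range of 12.3 to 19.6 CPM, whereas control 1 and control 2 had 108 and 135 CPM. With the muscle level as a covariate, chosen after seeing the data, the panel count was 5. Dmp1 (-1.56, adjusted p = 0.00588 over the 25 alone) and Phex (-1.39, adjusted p = 0.00588) then passed with Acp5, Tnfrsf11b and Ctsk, while Cyp24a1 (3.15, SE 1.03, adjusted p = 0.0556), Slc13a5 (1.18, SE 0.39, 0.0558) and Mepe (-2.47, SE 0.80, 0.0744) did not. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, had 1.42, and its 3 adenine libraries lay above all control libraries (adjusted p = 0.0929 over the 25 genes alone). Without adenine 3 Tnfsf11 had 0.69, and Cs had -0.78 without control 2, -1.03 without adenine 2 and -0.28 to -0.31 without control 3, adenine 1 or adenine 3. Col1a1 had 1.01, Alpl 0.63, Pth1r 0.55, Vdr 0.37 and Bglap 0.29. Hbb-bs (red cells) had 0.50 and Acta1 (skeletal muscle) had -1.17 with a standard error of 1.22. With 1 library left out Acta1 ran from -3.81 to -0.64.

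The citrate list held 16 tested genes, 7 with a positive and 9 with a negative fold change. Its median log2 fold change was -0.24 and its mean was 0.03, so the median and mean differed in sign while the list test pointed down (camera, adjusted p = 0.567; adjusted p = 0.742 with an estimated correlation). In edgeR no member passed, adjusted over the list alone or over all genes: 0 of 16 in each case. By the DESeq2 Wald test 2 of these 16 passed, adjusted over the list alone. The authors' deposited table called 1 of the 16 over all genes, Slc13a3 (adjusted p = 1.75e-04). That table also called Slc13a2, a list gene outside the 16 tested, higher (log2 fold change 6.47, adjusted p = 0.0103). Its counts were 1, 0 and 0 in the control libraries and 58, 16 and 5 in the adenine libraries. The highest was in adenine 1, where all 18 tested kidney tubule genes also had their highest CPM. Kidney RNA carried into that library was not tested as a source of the Slc13a2 counts. The smallest p values belonged to Slc13a3, a dicarboxylate carrier abundant in kidney (log2 fold change 4.16), and to Slc13a5, both with an adjusted p of 0.0743 over the list alone. Without adenine 2, 4 of 16 passed, adjusted over the list alone, among them Slc13a3 (4.62) and Slc13a5 (1.83) higher and the pyruvate dehydrogenase subunit gene Pdha1 (-1.61) lower. That fit keeps only adenine libraries with a low muscle level, so diet and muscle level cannot be told apart in it. Slc13a2, Slc13a3 and Pdha1 were chosen for mention here after their values were seen. The counts of Slc13a3 were 35, 10 and 8 in the control libraries and 630, 63 and 105 in the adenine libraries. The kidney tubule transcript Slc34a1, the phosphate transporter of the proximal tubule, also had its highest count in adenine 1, with counts of 93, 30 and 65 in the control libraries and 2184, 207 and 47 in the adenine libraries. Slc13a5 had its highest count, 934, in adenine 3, and 409 and 283 in adenine 1 and adenine 2.

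In the osteoclast list, all 18 genes had a positive fold change and the median was 1.32 (camera with a preset correlation of 0.01, adjusted p = 3.41e-12; adjusted p = 0.262 with an estimated correlation). Atp6v0d2, a proton pump subunit needed for osteoclast fusion, rose from 49.5 ± 8.23 to 157 ± 33.1 CPM (SD, n = 3 each). Ocstamp and Dcstamp, fusion receptors, rose by log2 fold changes of 2.71 and 1.65, and Oscar, a costimulatory receptor, by 2.03. Dcstamp was not among the genes named by the rule. Acp5, the tartrate-resistant phosphatase, rose from 464 ± 47.3 to 1315 ± 445 CPM, and Ctsk, the collagen-degrading cathepsin, from 689 ± 38.9 to 1803 ± 648 CPM (SD, n = 3 each). Of the 18 genes, 9 were also called higher in the authors' deposited table, which rests on the same counts. The perilacunar remodelling list shares Acp5, Ctsk, Atp6v0d2, Tcirg1 and Car2 with the osteoclast list. It had 5 of 12 genes higher, adjusted over the list alone, with a median of 0.82. Its camera adjusted p was 5.73e-06, and 0.489 with an estimated correlation. Macrophage genes moved the same way: Csf1r (1.35), Cd68 (1.505) and Adgre1 (1.46) rose, 3 of 15 genes adjusted over the list alone, with a list median of 0.92 (adjusted p = 3.88e-06; adjusted p = 0.622 with an estimated correlation). Without control 1, control 2 or adenine 3 the perilacunar count was 2 of 12, and without adenine 2 the macrophage count was 11 of 15. The macrophage median was 0.50 without adenine 3 and 0.42 with the muscle level as a covariate. Without control 3 and adenine 1 together, chosen after seeing the data, these counts were 2 of 12 and 0 of 15.

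Osteocyte markers had 6 genes lower and 1 higher of 19, adjusted over the list alone, with a median of -0.83 (camera adjusted p = 0.0241; adjusted p = 0.489 with an estimated correlation). Ackr3, an atypical chemokine receptor, fell from 44.8 ± 4.70 to 16.0 ± 3.72 CPM (SD, n = 3 each). Ptprz1, Fbln7 and Mepe fell, with log2 fold changes of -1.30, -2.46 and -2.43, and Tnfrsf19 rose by 1.28. The count was 1 of 19 without control 1 and 3 of 19 without control 2, adenine 1 or adenine 3, and the list call was lost without control 1 (adjusted p = 0.0807) and without adenine 2 (adjusted p = 0.141). The osteoblast and bone matrix list was called higher with a median of 0.59 (adjusted p = 0.00425; adjusted p = 0.641 with an estimated correlation), though 0 of 25 genes passed, adjusted over the list alone. Its smallest p values belonged to Col24a1, with a log2 fold change of -1.15, and Ibsp, with 1.52. The list was not called without control 2 (adjusted p = 0.0716) or without adenine 3 (median 0.27, adjusted p = 0.281), and adenine 2 lay below all control libraries; without adenine 2, 5 of 25 genes passed, adjusted over the list alone. With covariates chosen after seeing the data, the osteoblast call ended with the muscle level (median 0.13, adjusted p = 0.411). The osteocyte call ended with the kidney level (adjusted p = 0.0641) and 0 of its genes passed, at a median of -0.75 and with Ackr3 at -1.28 (SE 0.36, against 0.24 without the covariate) and Mepe at -2.44 (SE 1.01 against 0.68). With the replicate number as a block the osteocyte adjusted p was 0.0538.

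The nerve and Schwann cell list had a median of -2.13 (adjusted p = 7.91e-08; adjusted p = 0.262 with an estimated correlation). Sox10, the Schwann cell transcription factor, fell with a log2 fold change of -4.74, as did Prx (-3.04). The periosteal and tendon fibroblast list had a median of -1.90 (adjusted p = 4.59e-12; 0.262 with an estimated correlation). Comp, a cartilage and tendon matrix protein, fell with a log2 fold change of -2.24, as did Dpt (-3.30), the tenomodulin gene Tnmd (-2.71) and Clec3b (-3.69). In the chondrocyte list, Comp, Acan (aggrecan) and Chad fell, 3 of 9 genes adjusted over the list alone, with a median of -0.83. The camera adjusted p of this list was 0.00175, and 0.262 with an estimated correlation. Comp and Chad are also in the fibroblast list. Endothelial genes fell in 9 of 18 cases, adjusted over the list alone, with a median of -0.81 (adjusted p = 7.46e-07; adjusted p = 0.489 with an estimated correlation). Emcn, Cldn5, Kdr and Tie1 fell, with log2 fold changes of -1.12, -1.27, -1.24 and -0.998. The endothelial count was 2 of 18 without control 1, control 3, adenine 1 or adenine 3 and 16 of 18 without adenine 2. The fibroblast count was 7 of 20 without control 3, and with the kidney covariate 0 fibroblast, 0 endothelial and 0 chondrocyte genes passed. The list medians with that covariate were -1.44, -0.74 and -0.87, and standard errors of these members were wider: Dpt had -2.72 (SE 0.73 against 0.52), Emcn -1.16 (SE 0.30 against 0.20) and Chad -3.61 (SE 1.58 against 0.86). Without control 3 and adenine 1 together, 0 endothelial genes passed.

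**Figure D2:**
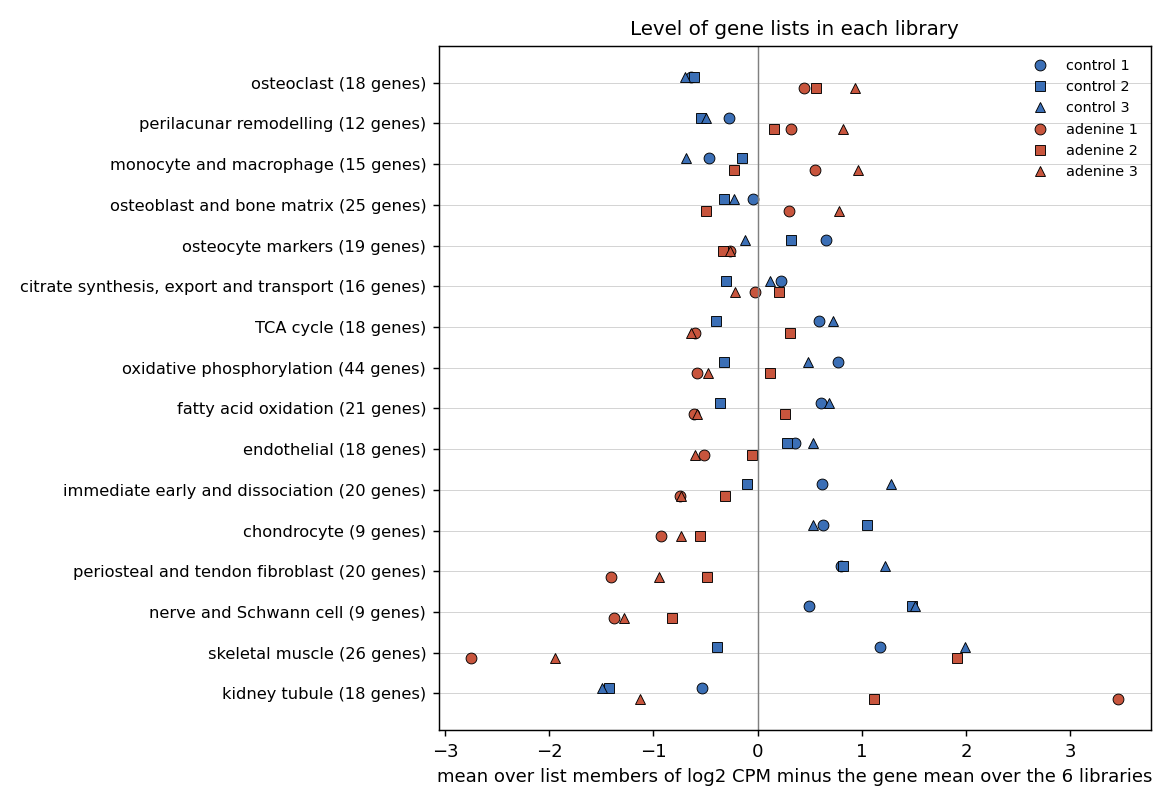
Level of 16 gene lists in each library: the mean over list members of log2 CPM minus each gene's mean over the 6 libraries (horizontal axis, log2 units), for control (blue) and adenine (red) libraries. Osteoclast levels are -0.69 to -0.61 in the control libraries and 0.44 to 0.93 in the adenine libraries, nerve and Schwann cell levels are 0.49 to 1.51 against -1.38 to -0.82, and the skeletal muscle level runs from -2.75 in adenine 1 to 1.99 in control 3.

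Mitochondrial energy metabolism lists were called lower with the preset correlation. Oxidative phosphorylation had a median of -0.71 with 43 of 44 genes negative (adjusted p = 1.75e-07), the TCA cycle -0.70 with 17 of 18 negative (adjusted p = 0.00278) and fatty acid oxidation -0.51 with 20 of 21 negative (adjusted p = 0.00425). With an estimated correlation the adjusted p was 0.641, 0.648 and 0.641 in that order, and 0 genes of each list passed, adjusted over the list alone. Ndufs8 of complex I had a log2 fold change of -0.75, Cycs (cytochrome c) -0.97, Idh3a -1.19, Sdhc -0.74, Acadvl -1.002 and Hadhb -0.98. The mitochondrially encoded genes, by contrast in sign, had a median of 0.34 and were not called (adjusted p = 0.144). They were called higher without control 1 (adjusted p = 0.0463), control 3 (0.0491) or adenine 3 (0.00100), with the muscle level as a covariate (median 0.74, adjusted p = 5.85e-07) and without control 3 and adenine 1 together (0.0259). Skeletal muscle markers moved with the energy lists. The muscle list was called lower with a median of -0.86 (adjusted p = 5.48e-05; adjusted p = 0.641 with an estimated correlation), its genes Mb, Pvalb and Myl1 having log2 fold changes of -2.12, -1.75 and -1.90 with standard errors of 1.05 to 1.23. Myh8, also of this list, had 2.40 (SE 1.68). Without adenine 2 these 4 genes had -4.50, -3.83, -4.50 and -2.49. Its level relative to the mean of the 6 libraries was 1.17, -0.38 and 1.99 in the control libraries and -2.75, 1.91 and -1.95 in the adenine libraries, and the TCA level was 0.59, -0.40 and 0.73 against -0.60, 0.31 and -0.64. With the muscle level as a covariate, an alternative chosen after seeing the data, the TCA median was -0.19 (adjusted p = 0.437), that of fatty acid oxidation -0.18 (adjusted p = 0.411) and that of oxidative phosphorylation -0.32 (adjusted p = 0.00914). The TCA call was also lost without control 3 (adjusted p = 0.0662) or adenine 3 (0.0560), and the fatty acid oxidation call without control 1 (0.0535), control 3 (0.0813) or adenine 3 (0.0560). Without control 3 and adenine 1 together the TCA (0.281), fatty acid oxidation (0.262) and muscle (0.337) calls were lost, the muscle median being 0.13. The muscle median was -0.39 without control 3, -0.34 without adenine 1, -3.52 without adenine 2, -0.39 without adenine 3 and -0.43 with the kidney covariate. Without adenine 2 the TCA median was -1.05 and that of fatty acid oxidation -0.82, and without control 1 the latter was -0.33 and that of oxidative phosphorylation -0.45. Adjusted over the list alone, 23 of 44 oxidative phosphorylation genes passed without control 2, and 3 of 18 TCA and 25 of 26 muscle genes passed without adenine 2.

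**Figure D3:**
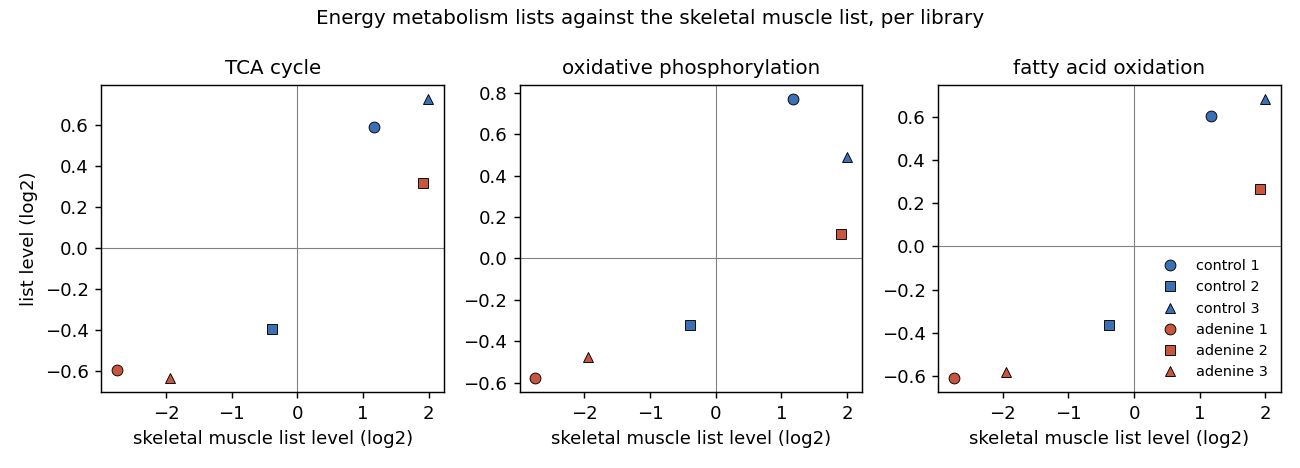
Level of 3 energy metabolism lists (vertical axes) against the level of the skeletal muscle list (horizontal axes), both as mean log2 CPM relative to the mean of the 6 libraries, one point per library. Adenine 2, with a muscle level of 1.91, has a TCA cycle level of 0.31, and control 2, with a muscle level of -0.38, has -0.40.

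Immediate early genes fell in 10 of 20 cases, adjusted over the list alone, with a median of -1.36 (adjusted p = 4.09e-07; adjusted p = 0.489 with an estimated correlation). Klf4, Egr3, Klf2 and Atf3 fell, with log2 fold changes of -1.44, -1.82, -1.14 and -2.25. With 1 library left out Atf3 ran from -2.64 to -1.38. The count was 0 of 20 without control 1 or adenine 1, 1 of 20 without control 3 or adenine 3, 1 of 20 with the muscle covariate, and 0 of 20 with the kidney covariate or without control 3 and adenine 1. With the kidney covariate the median was -1.15, and Klf4 had -1.40 (SE 0.38 against 0.25). With the muscle covariate the median was -0.97 and the list stayed called (camera adjusted p = 1.46e-05). Klf4, Egr3, Klf2 and Atf3 then had -1.45, -1.33, -0.92 and -1.65. In the adipocyte list 3 of 13 genes fell, adjusted over the list alone: Cidec (-2.91), Plin1 (-2.69) and Cfd (-1.68), with a list median of -0.78 (adjusted p = 5.42e-04; adjusted p = 0.622 with an estimated correlation). In the B cell list Ighm, Spib and Rag1 fell, 3 of 13 adjusted over the list alone, with a median of -0.82 (adjusted p = 7.69e-04; adjusted p = 0.622 with an estimated correlation). Rag1, needed for antigen receptor assembly, had 152 counts over the control libraries and 0 over the adenine libraries, at least 44.3-fold lower at a floor of 3 counts over the group. Of the 152 counts, 121 were in control 2, without which the bound is 12.8-fold. The B cell count was 1 of 13 without control 2, adenine 1 or adenine 3 and 5 of 13 without control 3, and the adipocyte count was 9 of 13 without adenine 2 and 5 of 13 without adenine 3. The adipocyte call ended with the muscle covariate (median -0.38, adjusted p = 0.0659), and 0 of 13 adipocyte genes passed with the kidney covariate, where the median was -0.85 and Cidec had -2.59 (SE 0.81 against 0.50). The adipocyte median was -0.46 without control 3 and -1.36 without adenine 2, and the B cell median -0.49 without control 2 and -1.65 without adenine 3. The B cell call ended with the stricter filter (adjusted p = 0.0544), and its count was 7 with the muscle covariate (median -1.75) and 1 with the kidney covariate (median -0.41) or without control 3 and adenine 1. The marrow stromal list had a median of -0.34 and 1 of 12 genes lower, adjusted over the list alone (list adjusted p = 0.0131; 0.622 with an estimated correlation); that gene, Grem1, a BMP antagonist, fell from 27.0 ± 5.72 to 3.16 ± 1.14 CPM (SD, n = 3 each). The stromal list was not called without adenine 2 (adjusted p = 0.231), with the kidney covariate (median -0.13, adjusted p = 0.235) or without control 3 and adenine 1 (median -0.17, adjusted p = 0.1002). Its count was 2 of 12 without control 1, and its median was -0.55 without adenine 3.

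The cell cycle, neutrophil and erythroid lists were called higher with the preset correlation, but 0 genes of each passed, adjusted over the list alone. Cell cycle genes had a median of 0.57 with 28 of 28 positive (adjusted p = 5.73e-06), neutrophil genes 0.85 (adjusted p = 8.97e-06) and erythroid genes 0.40 (adjusted p = 0.00175). With an estimated correlation the adjusted p was 0.641, 0.641 and 0.670 in that order. Cenpf, Aurkb and Cdk1 had log2 fold changes of 0.76, 0.76 and 0.74, Chil3, Mmp8 and Itgam had 2.33, 1.44 and 1.02, and Car1 and Rhag had 0.84 and 0.70. With 1 library left out Cenpf ran from 0.43 to 1.24, Aurkb from 0.45 to 1.39 and Cdk1 from 0.36 to 1.35. Chil3 ran from 1.85 to 3.44, Mmp8 from 0.97 to 2.19 and Itgam from 0.68 to 1.59. Car1 ran from 0.46 to 1.53 and Rhag from 0.31 to 1.43. Control 3 stood apart from the other libraries in these lists, at -1.55 for cell cycle, -2.26 for neutrophil and -1.61 for erythroid genes, and without it the erythroid list was not called (adjusted p = 0.738). The erythroid call also ended with the muscle covariate (median 0.18, adjusted p = 0.186) and the kidney covariate (median 0.13, adjusted p = 0.105), and the cell cycle call without control 3 and adenine 1 (median 0.03, adjusted p = 0.337). Without control 3 the cell cycle and neutrophil medians were 0.20 and 0.36. Without control 2 the cell cycle, neutrophil and erythroid medians were 1.17, 1.66 and 1.05, and without adenine 1 the erythroid median was 0.26. With the muscle covariate the cell cycle and neutrophil medians were 0.21 and 0.49. Without control 2, 13 of 20 neutrophil genes passed, adjusted over the list alone.

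No gene passed over all genes tested, so the 4 smallest p values in each direction, among protein-coding genes whose groups did not overlap, are given as genes that did not pass. The groups did not overlap in 16.5% of tested genes, against 10% by chance. Slc37a2, a phosphate-linked hexose phosphate antiporter of macrophages and osteoclasts, had a log2 fold change of 1.85, Eps8l1 of 3.69, Atp6v0d2 of 1.67 and the receptor kinase Mst1r of 1.89. Grem1 had -3.08, Wnt16, a Wnt ligand made by bone cells, -3.62, Itih5 -2.22 and Akap12 -1.87. Their adjusted p values in edgeR were 0.169 to 0.180. Without adenine 2, the edgeR count of genes over all genes was 298, with 27 higher and 271 lower, and it was 0 without any other single library. The fit without adenine 2 kept adenine libraries with muscle levels of -2.75 and -1.95, against 1.17, -0.38 and 1.99 in the control libraries. In it 25 of 26 muscle genes passed, adjusted over the list alone, so diet and muscle level cannot be told apart there. Of the 298 genes, 100 were called in the authors' deposited table. The authors' deposited table called 361 genes, 120 higher and 241 lower, among them the 8 genes named above, and the 327 of the 361 that were tested in edgeR all had an unadjusted p under 0.05 there. Both tests used the same counts, so this overlap is no independent support. In the simulation with these libraries' dispersions, DESeq2 gave 53 false calls.

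Of the lists not called, glycolysis had a median of -0.60 (adjusted p = 0.0824), hypoxia response -0.27 (adjusted p = 0.0824), circadian clock -0.55 (adjusted p = 0.0543) and Wnt signalling -0.24 (adjusted p = 0.366), the last with 2 of 23 genes lower, Wnt16 and Tnfrsf11b, adjusted over the list alone. The PTH and vitamin D response list had a median of -0.09 (adjusted p = 0.995), with Cyp24a1 higher and Tnfrsf11b and Nr4a1 lower, adjusted over the list alone. Phosphate and mineralization regulators had a median of -0.47 (adjusted p = 0.546), iron handling 0.21 (adjusted p = 0.110), inflammatory cytokines 0.20 (adjusted p = 0.263), interferon response -0.01 (adjusted p = 0.841) and lipid and sterol synthesis -0.15 (adjusted p = 0.372). Glucocorticoid response had a median of 0.04 and a mean of -0.06 (adjusted p = 0.660), and endoplasmic reticulum stress a median of 0.09 and a mean of -0.11, with the test pointing down (adjusted p = 0.995). Without adenine 2, glycolysis, hypoxia response and circadian clock were called lower (medians -1.31, -0.57 and -0.86, adjusted p = 0.00585, 0.00984 and 0.00430), with 9 of 19, 5 of 22 and 7 of 18 genes past the threshold, adjusted over the list alone. They were also called without control 2 (0.0470, 0.0470 and 0.0127), and the circadian clock list without control 1 (0.0274). Also without adenine 2, 4 of 22 glucocorticoid, 2 of 26 interferon and 1 of 21 lipid genes passed, adjusted over the list alone. The endoplasmic reticulum stress count was 1 of 20 without control 2, and the phosphate count 1 of 19 without control 2, control 3 or adenine 2, with a phosphate median of 0.17 without control 3. The PTH and vitamin D count of 3 was 0 without control 1 or control 3, 1 without adenine 1 or adenine 3 and 5 without adenine 2, and the Wnt count was 1 without control 1, control 2 or adenine 3. The PTH and vitamin D count was 0 with either covariate and without control 3 and adenine 1, and the Wnt count 1 with the muscle and 0 with the kidney covariate. Glycolysis and circadian clock were also called lower by the DESeq2 Wald test (adjusted p = 0.0219 each), limma-trend with each pseudocount, no filter and the stricter filter. Hypoxia response was also called by limma-trend and with no filter, and circadian clock with a prior count of 10 (0.0449). With the muscle covariate the glycolysis, circadian clock and hypoxia medians were -0.24, 0.013 and -0.11. None of these lists was then called (camera adjusted p = 0.411, 0.805 and 0.805). Their calls without adenine 2 come from the fit in which diet and muscle level cannot be told apart. Glucocorticoid response was called higher with the muscle covariate (median 0.39, adjusted p = 0.00272) and without control 3 and adenine 1 (median 0.58, adjusted p = 4.52e-04). The T and NK cell list had a median of 0.65 (adjusted p = 0.380) and the megakaryocyte and platelet list -0.19 (adjusted p = 0.995). With the muscle covariate the latter was called lower (median -1.12, adjusted p = 9.54e-05), with 7 of 14 genes past the threshold, adjusted over the list alone.

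The list calls rest on a preset correlation between genes: 20 of 36 lists were called with it, 7 higher and 13 lower, and 0 with an estimated correlation, while fry's directional test called 4, the osteoclast, chondrocyte, periosteal and tendon fibroblast, and nerve and Schwann cell lists. Leaving out any one library left 9 to 12 osteoclast genes, 6 to 8 nerve and Schwann cell genes and 7 to 11 fibroblast genes past the threshold.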

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

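The covariate fits, the fit without control 3 and adenine 1, limma voom and limma-trend on log2(FPKM + 0.1) or log2(FPKM + 10) were chosen after the data were seen. Apart from the fewer libraries or genes in a fit, the cause was not tested. Prior counts apply to list tests and robust moderation to gene tests only, and the stricter filter was set on the minimum count, not on the mean.

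Against 0 genes, the count over all genes was 361 (120 higher, 241 lower) by the DESeq2 Wald test and 66 (10 higher, 56 lower) with no filter. It was 1 lower, the microRNA gene Mir145a, by limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), and 3 lower with the muscle covariate (Wnt16, Myoc and Igfbp6), Mir145a, Myoc and Igfbp6 being named after their values were seen. Leaving out 1 library gave 0 to 298 (0 to 27 higher, 0 to 271 lower). Genes at an unadjusted p under 0.05 numbered 906 to 3133 with 1 library left out, 693 with the kidney covariate and 570 without control 3 and adenine 1. The panel count of 6 was 10 by DESeq2, 5 with the muscle covariate, 3 with log2(FPKM + 1), log2(FPKM + 0.1), voom or without control 3 and adenine 1, 2 with log2(FPKM + 10), 0 with the kidney covariate and 0 to 9 with 1 library left out. Of 36 lists, 0 were called with an estimated correlation, 4 by fry and 16 to 23 under every other setting.

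The deviations of same-numbered libraries from their group means had correlations of -0.039, -0.45 and -0.17. With 3 libraries per group this cannot exclude a pairing, and what the numbers mark is not known. With the replicate number as a block, 0 genes passed, 986 had an unadjusted p under 0.05, the panel count was 0, 19 lists were called and the citrate median was -0.29.

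The citrate median was -0.10 to -0.52 with 1 library left out. The direction of its test turned with the muscle covariate (median -0.039) and without control 3 and adenine 1 (-0.14), though it was called in neither. In 54 cases a direction turned for a result past the threshold in neither fit. For lists the direction is that of the test over all members, so a median can keep its sign. Besides the citrate list, the test turned in these lists (medians given). With the kidney covariate: PTH and vitamin D -0.022, endoplasmic reticulum stress 0.16, megakaryocyte 0.13. With the muscle covariate: PTH and vitamin D -0.048, T and NK cell -0.47. Without control 3 and adenine 1: PTH and vitamin D 0.27, circadian clock -0.041, erythroid -0.15, called before, T and NK cell -0.18. PTH and vitamin D also turned with voom (-0.074), the block (-0.064) and a prior count of 0.1 (-0.089), and endoplasmic reticulum stress with the stricter filter (0.092) and log2(FPKM + 10) (0.090). Genes turned (log2 fold changes) with the muscle covariate: Cs 0.027, Acly -0.22, Slc25a1 -0.045, Idh2 0.38, Fgf23 0.19, Bglap -0.93; without control 3 and adenine 1: Acly -0.082, Slc25a1 -0.12, Idh2 0.11, Bglap -0.25, Hbb-bs -0.16; with the kidney covariate: Slc25a1 -0.012. Myh8 turned with voom (-1.06) and the block (-0.62).

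Leaving out 1 library, medians ran from -0.31 to 0.14 (PTH and vitamin D), -0.22 to 0.32 (glucocorticoid), -0.090 to 0.31 (interferon), -0.057 to 0.21 (endoplasmic reticulum stress), 0.19 to 0.86 (T and NK cell), -0.46 to 0.88 (megakaryocyte), -0.20 to 0.60 (mitochondrially encoded), -0.53 to 0.17 (phosphate), 0.0039 to 0.46 (inflammatory), 0.094 to 0.38 (iron), -1.31 to -0.32 (glycolysis), -0.57 to -0.058 (hypoxia), -0.86 to -0.22 (circadian clock) and -0.32 to -0.012 (Wnt). Log2 fold changes ran from -0.11 to 0.38 (Acly), -0.028 to 0.22 (Slc25a1), -0.58 to 0.13 (Idh2), -1.04 to 0.023 (Fgf23), -0.15 to 0.74 (Bglap), -0.0073 to 0.59 (Vdr) and -2.49 to 2.98 (Myh8). Of the other comparisons across settings, 1881 gene values and 675 list values kept direction and side of the threshold, 102 and 32 gained a call and 56 and 63 lost one. With the kidney covariate 0 osteocyte, endothelial, fibroblast, chondrocyte, adipocyte, immediate early, PTH and vitamin D, and Wnt genes passed, adjusted over the list alone, but 11 osteoclast and 7 nerve genes did. With it Wnt16 had -3.28 (SE 0.73, against -3.62 and 0.48 without it) and Kdr -1.27 (SE 0.44, against -1.24 and 0.29).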

Other observations

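The tests in this part were chosen only after the result was seen, other than the counts over splits for all genes, lists called and the citrate median, which were set with the real values in view but before other splits were counted. Transcripts that textbooks place in the kidney tubule were measured in these bone libraries. A list of 18 tested tubule genes had a median log2 fold change of 3.03 with all 18 positive, and 0 passed, adjusted over the list alone. Kap, an abundant proximal tubule transcript, had 2810, 547 and 481 counts in the control libraries and 14898, 6730 and 1177 in the adenine libraries. Umod, made by the thick ascending limb, had 256, 76 and 17 against 987, 361 and 54, and Slc12a3, of the distal tubule, had 13, 25 and 18 against 544, 76 and 6. Of the 18 genes, 3 were called in the authors' deposited table, all 3 of them higher.

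The rise of kidney transcripts may come from kidney RNA carried into some libraries. In 18 of 18 tubule genes, which belong to separate nephron segments, the highest CPM was in adenine 1, and the list level in adenine 3 (-1.13) lay within the control range (-1.49 to -0.53). As a whole source of the Slc13a5 difference this is argued against. With the kidney level as a covariate its log2 fold change was 1.92 (SE 0.54, unadjusted p = 0.0105 in edgeR's test fitted across all genes). Without the covariate it was 1.59 (SE 0.46, unadjusted p = 0.00929 in the same test). Its call over the 25 genes nevertheless ended with the covariate (adjusted p = 0.110), and no panel gene passed. For Slc13a3 the value went from 4.16 (SE 1.06) to 2.17 (SE 0.69) and for Cyp24a1 from 3.91 (SE 0.99) to 1.88 (SE 0.75), so a carried-in part and a part of bone's own cannot be told apart with 6 libraries. An effect of the diet on bone cells stays open for all 3 genes.

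The lower energy metabolism lists could follow how much muscle RNA each library held. The TCA cycle list followed the muscle level over the 6 libraries with Pearson r = 0.927 (exact permutation p = 0.025, adjusted 0.0833 over 10 relations) and Spearman rho = 0.886 (exact permutation p = 0.0333, adjusted 0.146), and r was 0.873 without adenine 1 and adenine 3. Fatty acid oxidation had r = 0.924 (exact permutation p = 0.0236, adjusted 0.0833) and rho = 0.943 (p = 0.0167, adjusted 0.146), and oxidative phosphorylation r = 0.852 (exact permutation p = 0.0472, adjusted 0.118) and rho = 0.829 (p = 0.0583, adjusted 0.146), with r = 0.838 and 0.631 without those 2 libraries. Glycolysis, a list not called, had r = 0.978 (exact permutation p = 0.00694, adjusted 0.0694) and rho = 0.829 (p = 0.0583, adjusted 0.146). Its r was 0.875 without those 2 libraries. With the muscle level as a covariate the medians were -0.19 (SD over members 0.24) for the TCA cycle and -0.18 (SD 0.24) for fatty acid oxidation, against -0.70 (SD 0.36) and -0.51 (SD 0.45) without it, and both calls ended. For oxidative phosphorylation the median was -0.32, still called with the preset correlation (adjusted p = 0.00914) but not with an estimated one (adjusted p = 0.861), so a remaining effect of the diet cannot be told apart from the muscle share there.

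The muscle share as the source of the lower nerve and fibroblast lists is argued against: with the muscle level as a covariate 8 of 9 nerve and Schwann cell genes and 13 of 20 fibroblast genes passed, adjusted over the list alone, against 7 and 11 without it. Nerve, periosteum and vessels could also have been trimmed differently at dissection. All adenine libraries lay below all control libraries in 4 of 5 soft tissue lists (fibroblast, nerve, chondrocyte and endothelial, not adipocyte), which a response of these cells to the diet would give too, so the design keeps trimming and response together and they cannot be told apart.

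The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. Over all genes, all 10 splits gave at least the real count of 0, which no count can be below, so this comparison decides nothing. Apart from the highest, the other splits also gave 0 genes. The highest other split gave 736 genes. That split set control 1, control 3 and adenine 2, which have the highest muscle levels, against the rest, and points to a structure of the samples apart from the diet. At an unadjusted p under 0.05, 2 of 10 splits gave at least the real 1671 genes (highest other 3752). For lists called, 2 of 10 gave at least the real 20 (highest other 22). For the absolute citrate median, 5 of 10 gave at least 0.24 (highest other 0.58). The split counts of the panel and of 6 lists were chosen after their real counts were seen, and these 6 lists had the highest real counts of all lists, which favours the real grouping, so nothing is read from them. At 1 of 10 splits each, the real split gave 6 panel genes (highest other 5), 12 osteoclast genes (highest other 1), 11 fibroblast, 7 nerve and 9 endothelial genes (highest other 0 each), 10 immediate early genes (highest other 6) and 7 osteocyte genes (highest other 2).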
